A study of Mus musculus with 6 samples.

How the data were processed

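Transcript levels were measured in hepatic progenitor cells from mouse control livers, with 3 samples of genotype Egfr fl/fl and 3 of genotype Met fl/fl, on 6 Illumina arrays of 1 colour. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with a Qiagen kit and biotin-labelled cRNA was made with an Ambion kit for Illumina arrays. Per the submitters' processing notes, the arrays were processed with GenomeStudio 2011.1. The array model and annotation version are not given in the sources used here.

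The deposited tables held 3 kinds of value. The first was a non-normalized intensity per probe on a linear scale. It fell below 0 for 26.9% to 31.1% of probes on each array, so a background had been subtracted before it was deposited. The second was a detection p-value per probe, deposited beside each intensity and named per the file headers. Its step of 0.00125 corresponds to 798 negative control probes. The third was a normalized intensity in the deposited matrix of values. Its columns nearly share their quartiles and rank the probes as the non-normalized columns do (Spearman 1 on each array), so the authors' matrix is on a linear scale, quantile normalized, with no gene centring. The column medians ran from 7.51 to 7.57 units. The detection p-values imply 1 negative control far brighter than the others on each Met fl/fl array, where the lowest signal above all negative controls was 319, 391 and 335 units, against 37.7, 33.8 and 42.4 units with at most 1 control above. On Egfr fl/fl replicates 1, 2 and 3 these values were 40.0, 38.7 and 75.9 units against 34.3, 30.6 and 34.3 units, so replicate 3 also had 1 control above the others, by less.

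Values were computed from the non-normalized intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp, with the mean and SD of the negative controls inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized on the log2 scale. The offset keeps dim probes stable and compresses their differences, so the change of low genes is understated. Quantile normalization gives every array the same distribution and removes any difference in total RNA per cell. Probes with a detection p under 0.05 on at least 3 arrays were tested, 11578 of 25697. Each probe was fitted with lmFit and eBayes with a variance trend, with no covariate, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. A gene with several tested probes was represented by the brightest over all arrays. Of 2208 genes with more than 1 tested probe, 1213 had at least 1 probe past the threshold, 522 had every probe past it in 1 direction, and 15 had probes past it in opposite directions.

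Every difference is Met fl/fl minus Egfr fl/fl. A probe not detected on 1 or more arrays of its dimmer group has only a bound there. The bright group's mean log2 value was set against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. No array detected the probe in the dim group for 142 called genes in Egfr fl/fl and 190 in Met fl/fl. Differences given for a gene's other probes, or with arrays left out, are fitted values without a bound.

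Gene symbols came from the deposited table. Of 18138 distinct symbols, 14307 were current in the RefSeq gene table for assembly GRCm38.p6, 2906 were updated through a synonym of 1 gene, and 925 were kept as given. Symbols of 31 probes had been turned into dates and named no gene. No genome was used here, and the gene table served for names, chromosomes and neighbours.

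The rule for the genes named, fixed before the data were examined, took Egfr and Met and the 12 genes with the largest difference in each direction among those past the threshold whose 3 values in a group all lay above those of the other, leaving out predicted or unnamed models. It also took up to 2 members in each direction past the threshold from each gene list, or the 1 member with the largest difference where none passed. The 38 lists were written before the data were examined, and 33 had at least the 5 tested members needed for a test. They were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists.

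Alternatives covered the background correction, the deposited normalized values, median scaling, cyclic loess, an offset of 50, no filter or a detection p under 0.01 on all 6 arrays, the variance model, array weights, the replicate number as a block, the mean of a gene's probes, and each array left out in turn. Alternatives chosen after seeing the data were a robust estimate of the negative controls' level and spread and a fit with Egfr fl/fl replicate 3 as the only Egfr fl/fl array. No 2 arrays held identical values over most probes. The fit was tested on simulated data for this comparison, with 8565 genes and 200 changed ones in each of 10 sets. It recovered 19.2% of changes of 0.5 on the log2 scale, 91.6% of changes of 1 and 100% of changes of 2, with 5.53% false calls among all calls. The simulated sets held far fewer changed genes than the 3543 called in the real data, and their noise was independent between genes. The adjusted threshold depends on the share of changed genes, so these rates describe the simulated setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.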

Results

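RNA from mouse hepatic progenitor cells was profiled on 6 Illumina bead arrays, each read in 1 colour after labelling with biotin. Hepatic progenitor cells are immature liver epithelial cells that can give rise to both hepatocytes and bile duct cells. The cells came from control livers of C57BL/6 mice that carried floxed alleles, with 3 samples from Egfr fl/fl livers and 3 from Met fl/fl livers. Floxed alleles are flanked by recombination sites and stay intact until a recombinase is present, so neither gene is known to be deleted in these samples. Egfr encodes the epidermal growth factor receptor and Met the receptor for hepatocyte growth factor. Each array held 25697 probes. The mean deposited intensity was 241, 248 and 321 units on Egfr fl/fl replicates 1, 2 and 3, and 398, 289 and 275 units on Met fl/fl replicates 1, 2 and 3. Between 43.8% and 45.3% of probes were detected above the negative controls on each array. The number of arrays, 3 per group, limits the precision of every value. The labels do not say whether the samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Slide and processing batch are not given in the labels. By the detection p-values, the lowest signal above all negative controls was 319, 391 and 335 units on the Met fl/fl arrays, 75.9 units on Egfr fl/fl replicate 3 and lower on Egfr fl/fl replicates 1 and 2. With at most 1 control above, it was 30.6 to 42.4 units on every array. If the groups were run on different slides, slide and genotype cannot be separated for any of the differences. The same holds for animal or culture if each group came from only 1.

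The comparison between the genotypes asks how far progenitor cells from the 2 kinds of control liver share an expression profile. Met fl/fl cells had higher transcript levels of the protease inhibitor Serpina3h, the organic anion transporter Slco4a1, the cell-surface protein Psca, the tight junction protein Cldn6, the signalling ligand Wnt4 and genes of mitosis and cholesterol synthesis. Egfr fl/fl cells had higher levels of the secreted protein Wfdc2, the membrane glycoprotein Pdpn, the glutathione transferase Gsta3, the intermediate filament gene Nes, and genes of inflammation and of the unfolded protein response. These list results hold at a preset correlation between genes, and with an estimated correlation 0 of 33 lists passed. Among the called lists only cholesterol synthesis had an estimate above the preset, so a higher correlation does not account for the loss of the others. Of 8565 genes tested with limma, 3543 (41.4%) passed the threshold after Benjamini-Hochberg adjustment, 1954 of them higher in Met fl/fl and 1589 higher in Egfr fl/fl. Among these, 1345 differed at least 2-fold, with 659 higher in Met fl/fl and 686 higher in Egfr fl/fl. At 8-fold or more 22 genes were higher in Met fl/fl and 76 higher in Egfr fl/fl, or 21 and 67 with signals under the detection limit raised to it. The 3 values of each group did not overlap in 4456 genes (52.0%), where chance gives 10%. With median scaling in place of quantile normalization 2353 genes passed, 1131 of them higher in Met fl/fl.

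The arrays separated by genotype. Pearson r over tested probes ranged from 0.967 to 0.992 within a group and from 0.891 to 0.921 between groups, and the first principal component took 78.8% of the variance. Egfr fl/fl replicate 3 stood apart from the others of its group on the second component. It lay nearer to the Met fl/fl mean than to the mean of Egfr fl/fl replicates 1 and 2 in 533 of the 3543 called genes (15.0%), in 136 of the 2-fold genes and in 3 of the 8-fold genes. Without it 4390 genes passed, 3431 of them among the 3543 and in the same direction. With replicate 3 as the only Egfr fl/fl array, a setting chosen after seeing the data, 2414 genes passed and 2145 of these were called in the same direction with all arrays. The lone array is assumed there to vary like the Met fl/fl arrays.

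**Figure D1:**
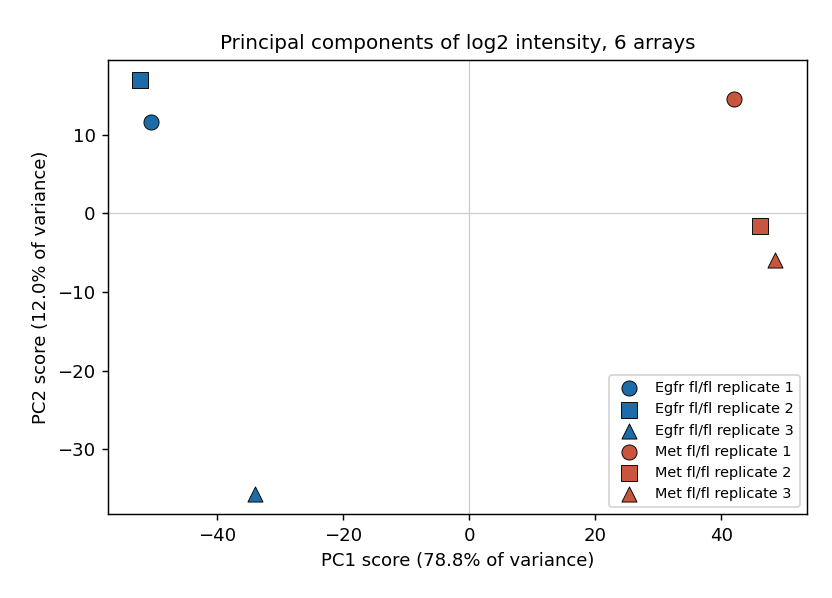
Scores of the 6 arrays on the first principal component (horizontal, 78.8% of the variance) and the second (vertical) of log2 intensity over tested probes; colour gives the genotype and the marker shape the replicate. The genotypes lie on opposite sides of the first component, and Egfr fl/fl replicate 3 has the lowest score on the second, -35.6.

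Serpina3h had the largest fitted difference among named genes higher in Met fl/fl. Its log2 intensity was 11.15 ± 0.07 (SD, n = 3) in Met fl/fl, and it was not detected on any Egfr fl/fl array, so the difference is at least 75.2-fold (limma adjusted p = 3.63e-09). Where a gene was not detected on 1 or more arrays of its dimmer group, the fold is a lower bound: the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Slco4a1 was at least 63.1-fold higher in Met fl/fl, Lxn, an inhibitor of carboxypeptidases, at least 37.1-fold, Cldn6 at least 28.0-fold and Renbp, the renin-binding protein, at least 13.1-fold. Psca reached 11.07 ± 0.08 in Met fl/fl and was at least 56.2-fold higher there, with 2 of 3 Egfr fl/fl arrays detecting it. Cyba, a subunit of the NADPH oxidase, was at least 35.2-fold higher and was detected on 1 Egfr fl/fl array. Genes detected on all 6 arrays included Sphk1, a sphingosine kinase, with a log2 difference of 3.78 ± 0.16 (13.7-fold), and Wnt4 with 3.42 ± 0.21 (10.7-fold). The kinase subunit Camk2b, detected on 1 Egfr fl/fl array, was higher in Met fl/fl by at least 3.59 on the log2 scale. The GTPase-activating protein Arap3 and the integrin subunit Itgb6, each detected on 2 Egfr fl/fl arrays, were at least 9.92-fold and 10.2-fold higher. The other probes of Itgb6 gave log2 differences of 2.68 and 0.66.

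In the other direction Wfdc2 read 12.76 ± 0.14 (SD, n = 3) in Egfr fl/fl and was detected on 1 Met fl/fl array, a difference of at least 216-fold (adjusted p = 1.50e-09). Pdpn was not detected on any Met fl/fl array and was at least 163-fold higher in Egfr fl/fl. The same held for the scavenger receptor family gene Scarf2 (at least 57.0-fold), Palmd (at least 59.7-fold), Nes (at least 47.5-fold), Pdzk1ip1 (at least 31.3-fold) and the receptor Gpr176 (at least 27.4-fold). The uroplakin Upk1b was 60.9-fold higher in Egfr fl/fl, with detection on all 6 arrays. Gsta3 was 58.8-fold higher by its brightest probe, and its other tested probe gave a log2 difference of -2.28. For Nes the other probe gave -3.44, and for Palmd the others gave -6.19 and -1.44. These differences of other probes are fitted values, not bounds, and may rest on undetected signals in Met fl/fl. Egfr fl/fl replicate 3 read higher than replicates 1 and 2 for Scarf2 (log2 intensity 11.45 against 10.46 and 10.43) and for Nes (11.11 against 10.06 and 10.38). Fstl1, a secreted glycoprotein, was 39.0-fold higher and the transcriptional cofactor Lbh 32.9-fold higher in Egfr fl/fl. Sirpa, a transmembrane signal regulatory protein, was detected on 1 Met fl/fl array and was at least 35.8-fold higher in Egfr fl/fl.

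**Figure D2:**
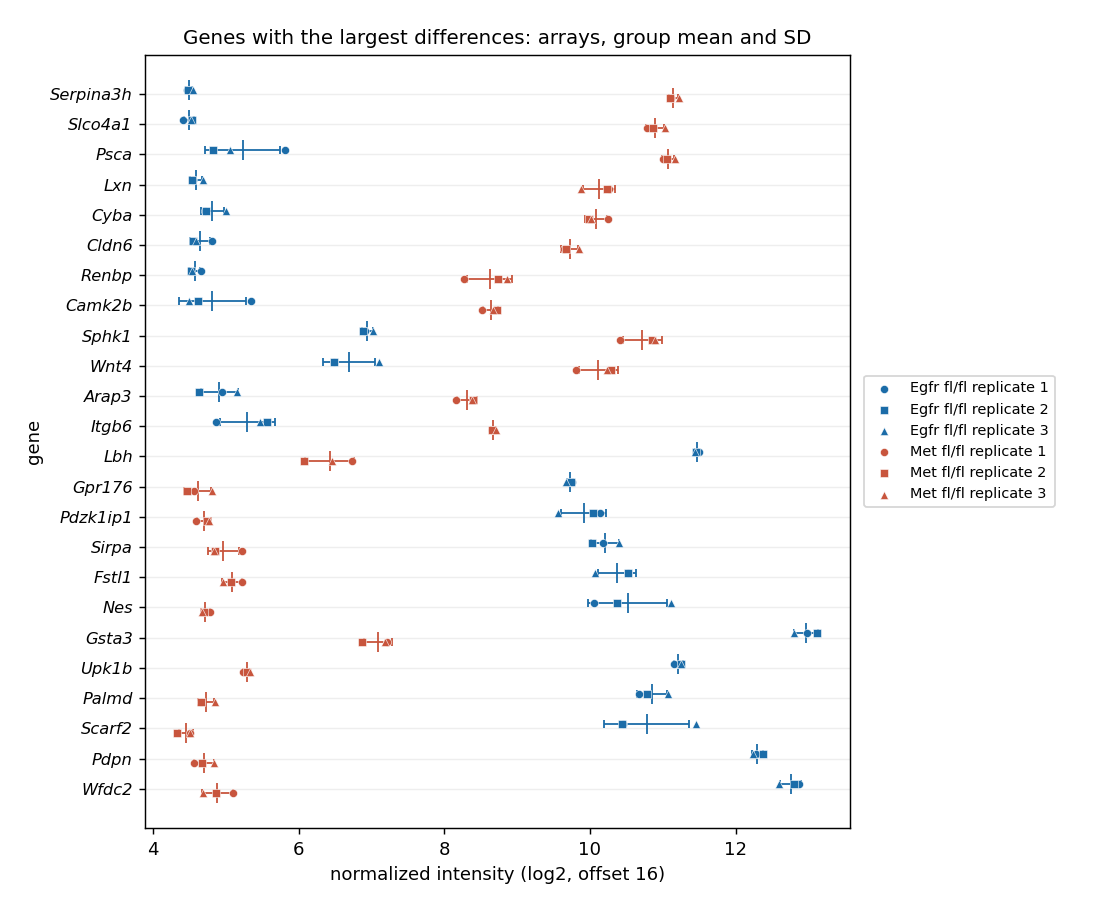
Normalized log2 intensity (horizontal) of the 12 genes with the largest differences in each direction (vertical), with a marker per array, a vertical tick at the group mean and a bar of 1 SD for n = 3. The genes were chosen for values that do not overlap between the genotypes; values near 4.9 or below lie at the detection limit.

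Of the floxed genes only Egfr could be tested. The brightest Egfr probe read 9.43 ± 0.21 (SD, n = 3) in Egfr fl/fl and 8.996 ± 0.072 in Met fl/fl, which is 1.35-fold higher in Egfr fl/fl (log2 difference -0.43 ± 0.15 SE, limma adjusted p = 0.0425). An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. A further Egfr probe differed by -0.61 (adjusted p = 0.0199) and another by -0.35 (adjusted p = 0.139), while the remaining probe was too dim to test. The call for the brightest probe ended when Egfr fl/fl replicate 2 (adjusted p = 0.151), Met fl/fl replicate 1 (0.0964), replicate 2 (0.104) or replicate 3 (0.0938) was left out, and with Egfr fl/fl replicate 3 as the only Egfr fl/fl array (0.0663). Median scaling (0.348), no filter (0.0866), no variance trend (0.0588) and array weights (0.0519) ended it too. It was kept in 11 of 20 alternative settings, over which the adjusted p ranged from 0.0282 to 0.348. The single Met probe was detected on Egfr fl/fl replicates 1 and 2 and on 0 of the 3 Met fl/fl arrays, and was not tested. Where these probes lie relative to the floxed exons is not given in the sources used here, and the samples are controls, so the levels do not check the labels.

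Gene lists written before the data were examined were tested with camera at a preset correlation, 33 lists having at least 5 tested members. In all, 7 passed, 2 higher in Met fl/fl and 5 higher in Egfr fl/fl. With a correlation estimated from these arrays 0 of the 33 passed after adjustment and 7 had an unadjusted p under 0.05, so each of the 7 is given with that adjusted p. Among the called lists only cholesterol synthesis had an estimate above the preset 0.01, at 0.065. The others ran from -0.045 (YAP and Hippo pathway) to 0.0052 (G2/M phase), so a higher correlation does not account for their loss. For G2/M phase the unadjusted camera p was 6.82e-08 at the preset and 0.00504 with the estimate. For the unfolded protein and amino acid stress response, with an estimate of -0.031, it was 6.10e-05 and 0.0113. The loss of these lists is therefore no evidence of correlation between their genes, and its cause was not tested. By fry, which asks whether a list's genes move one way without comparing them with other genes, 21 lists passed.

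Genes of the G2 and M phases of the cell cycle were higher in Met fl/fl. Of 17 tested members 14 rose and 0 fell, 14 also passing when adjusted over the list alone, with a median log2 difference of 1.52 (camera adjusted p = 2.25e-06; adjusted p = 0.113 with an estimated correlation). The mitotic kinesin Kif11 rose by 1.81 ± 0.30 (SE) on the log2 scale and Cdc20, an activator of the anaphase-promoting complex, by 1.66 ± 0.17. The other probes of Cdc20 gave 2.16, 1.98 and 0.78. With Egfr fl/fl replicate 3 alone Kif11 differed by 1.14. The median of the list was 0.90 when dim probes were kept. Genes of cholesterol synthesis were also higher in Met fl/fl, with 13 of 21 members up and 0 down, 14 passing when adjusted over the list alone, and a median of 0.83 (adjusted p = 0.000503; adjusted p = 0.225 with an estimated correlation). The mevalonate pathway enzyme Mvd rose 4.81-fold and Lss, which forms lanosterol, 3.16-fold. Of 26 tested genes of DNA replication and S phase 2 rose and 8 fell, 10 passing when adjusted over the list alone, with a median of -0.25 (adjusted p = 0.334). Without Egfr fl/fl replicate 3 the counts were 3 and 12, and with it alone the median was -0.047.

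Inflammatory cytokines and chemokines were higher in Egfr fl/fl, with 15 of 24 members in that direction, 3 in the other and 19 passing when adjusted over the list alone. Their median was -1.08 (camera adjusted p = 6.24e-05; adjusted p = 0.113 with an estimated correlation), and -0.18 when dim probes were kept. The chemokine Cxcl16 differed by -3.03 ± 0.17 (SE) and the adhesion molecule Icam1 by -2.68 ± 0.13. Against that direction the cytokine Il11 was 9.95-fold higher in Met fl/fl and Il18 1.89-fold higher. In the list of the unfolded protein and amino acid stress response 13 of 24 members were higher in Egfr fl/fl and 1 in Met fl/fl, 16 passing when adjusted over the list alone (median -0.61, adjusted p = 0.000503; adjusted p = 0.124 with an estimated correlation). The counts were 13 and 2 without Egfr fl/fl replicate 3. Trib3, a pseudokinase induced by this stress, was 4.90-fold higher in Egfr fl/fl by its brightest probe, with log2 differences of -0.76 and -0.72 on the others against -2.29. For the chaperone Calr the Egfr fl/fl arrays spread widely (8.55 ± 1.93, SD): the log2 difference was -3.16, but -0.99 with Egfr fl/fl replicate 3 alone and -4.27 without it. Herpud1, which acts in the degradation of proteins of the endoplasmic reticulum, was the member higher in Met fl/fl, by 0.47, and did not pass with median scaling (adjusted p = 0.144).

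Targets and components of the YAP and Hippo pathway were higher in Egfr fl/fl in 10 of 20 members and higher in Met fl/fl in 2, with 14 passing when adjusted over the list alone (median -0.52, camera adjusted p = 0.0120; adjusted p = 0.224 with an estimated correlation). The median was -0.31 when dim probes were kept. Besides Fstl1, the transcription factor Tead2 was 5.69-fold higher in Egfr fl/fl, whereas the phosphatase Ptpn14 was 2.52-fold higher and the receptor kinase Axl 1.60-fold higher in Met fl/fl. For the heat shock response 7 of 15 members were higher in Egfr fl/fl and 1 in Met fl/fl, with 9 passing when adjusted over the list alone (median -0.48, adjusted p = 0.0190; adjusted p = 0.225 with an estimated correlation). Leaving out Egfr fl/fl replicate 3 gave 9 and 2. The small heat shock protein Hspb8 was at least 14.6-fold higher in Egfr fl/fl, with 1 of 3 Met fl/fl arrays detecting it, and Hspa8 14.3-fold higher, with an SD of 1.09 on the log2 scale in Egfr fl/fl and of 0.78 in Met fl/fl. The log2 difference of Hspa8 was -4.48 without Egfr fl/fl replicate 3 and -2.57 with it alone. The inducible chaperone Hspa1a ran the other way, at least 2.00-fold higher in Met fl/fl, with 1 Egfr fl/fl array detecting it. Hypoxia response genes were higher in Egfr fl/fl in 7 of 14 members and in Met fl/fl in 2, with 9 passing when adjusted over the list alone (median -0.60, adjusted p = 0.0375; adjusted p = 0.225 with an estimated correlation). Among them P4ha2, a collagen prolyl hydroxylase, was 3.58-fold and the angiogenic factor Vegfa 2.80-fold higher in Egfr fl/fl, while Ddit4 was 2.35-fold higher in Met fl/fl. With Egfr fl/fl replicate 3 alone both lists missed the threshold, at 0.0554 for heat shock (median -0.29) and 0.0824 for hypoxia (median -0.37). The hypoxia list also missed it with only probes at a detection p under 0.01 on all 6 arrays (median -0.11, camera adjusted p = 0.475). With cyclic loess it missed it too (median -0.54, camera adjusted p = 0.0557). Its median was -0.20 when dim probes were kept.

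**Figure D3:**
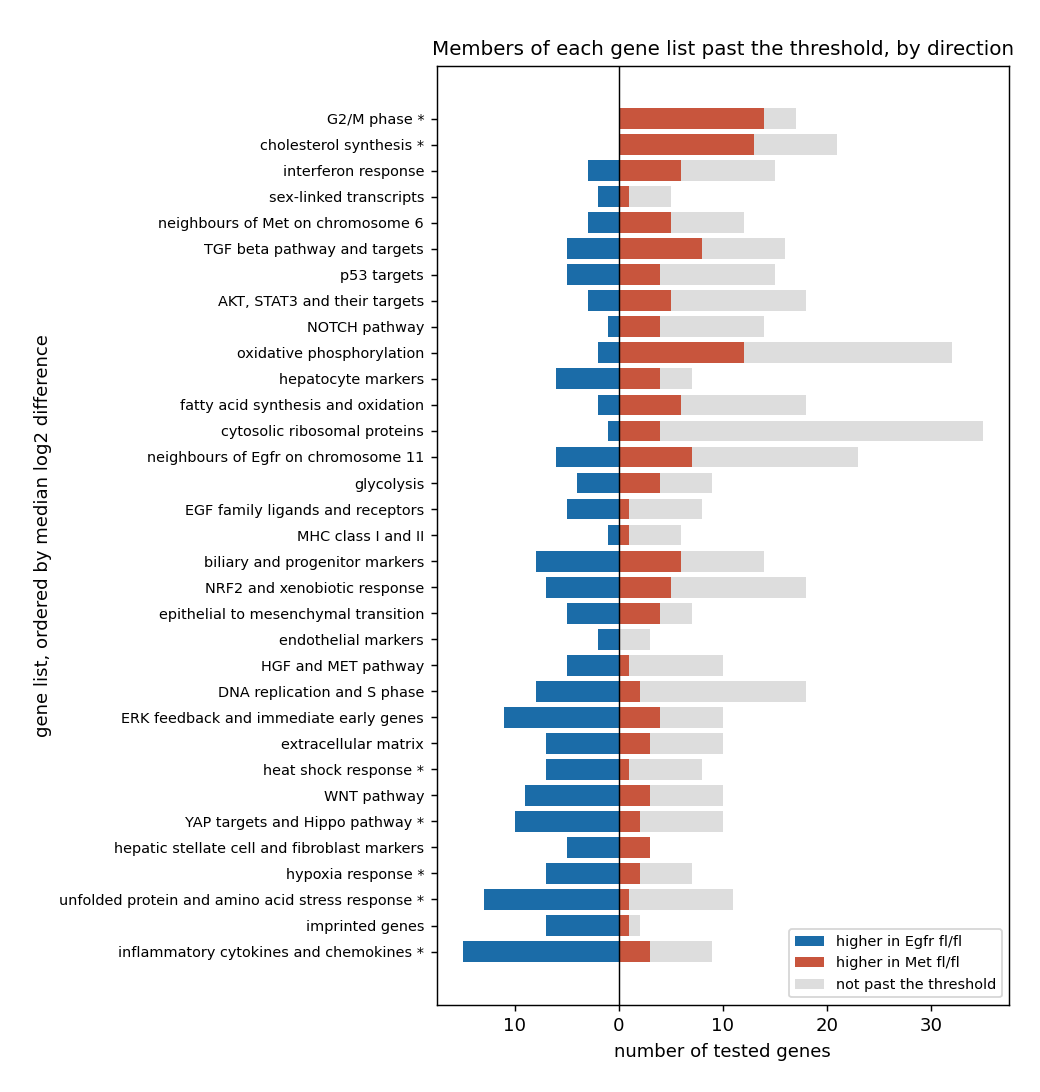
Number of tested members (horizontal) of each of the 33 gene lists (vertical, ordered by median log2 difference) that were higher in Egfr fl/fl, drawn to the left of 0, higher in Met fl/fl, drawn to the right, or not past the threshold, in grey. An asterisk marks the 7 lists past the camera threshold at the preset correlation; G2/M phase stands at the top with 14 members up and 0 down, and inflammatory cytokines and chemokines at the bottom with 15 down and 3 up.

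Markers of liver cell types moved in both directions, and many listed markers were not tested. Those tested were 22 of 31 biliary and progenitor markers and 13 of 39 hepatocyte markers. For stellate cells and fibroblasts 8 of 26 markers were tested, and for endothelium 5 of 20. Of 22 tested biliary and progenitor markers 6 were higher in Met fl/fl and 8 in Egfr fl/fl, with 16 passing when adjusted over the list alone (adjusted p = 0.667). Their median was -0.10 and their mean 0.14. With only probes at a detection p under 0.01 on all 6 arrays the list passed as higher in Egfr fl/fl (median -0.49, camera adjusted p = 0.0271). That filter drops genes undetected on any array, among them Cldn6 and Foxa1, both higher in Met fl/fl, so it is tied to the comparison. Without Egfr fl/fl replicate 3 the median over the 22 tested markers was 0.0034. Next to Cldn6 the pioneer factor Foxa1 was at least 7.21-fold higher in Met fl/fl, where Egfr fl/fl had detection on 2 arrays. The biliary transcription factor Sox9 was 3.68-fold and the hyaluronan receptor Cd44 3.49-fold higher in Egfr fl/fl. Hepatocyte markers split as 4 of 13 higher in Met fl/fl and 6 in Egfr fl/fl, 10 passing when adjusted over the list alone (adjusted p = 0.354), with a median of 0.10, or 0.062 without Egfr fl/fl replicate 3, and a mean of -0.69. The test placed the list higher in Egfr fl/fl, against the sign of its median, and with median scaling it passed in that direction (median 0.047, adjusted p = 0.0385). The hepatocyte transcription factor Hnf4a was 2.69-fold higher in Met fl/fl and the apolipoprotein Apoa1 at least 2.37-fold, whereas the plasma protein Hpx was 9.78-fold and Serpina1b at least 7.89-fold higher in Egfr fl/fl. Their other probes gave log2 differences of -2.36 and -2.38. Among 8 tested markers of hepatic stellate cells and fibroblasts 3 were higher in Met fl/fl and 5 in Egfr fl/fl, with 8 passing when adjusted over the list alone (adjusted p = 0.354). The collagen genes Col5a1 (3.71-fold) and Col6a1 (2.52-fold) were higher in Met fl/fl. The smooth muscle actin gene Acta2, at least 17.7-fold, and Vim, at 2.96-fold, were higher in Egfr fl/fl. The fold of Acta2 rests on 1 of 4 probes, which no Met fl/fl array detected, with a log2 bound of -4.14. On that probe Egfr fl/fl replicate 3 read 8.34, against 9.36 and 9.57 on replicates 1 and 2. The other probes of Acta2 gave fitted differences of -1.11, -1.05 and -0.51, the last not past the threshold. In the endothelial list 0 of 5 members rose and 2 fell in Met fl/fl, Esam 6.22-fold and Flt1 4.78-fold lower than in Egfr fl/fl (adjusted p = 0.313).

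Few blood cell markers were bright enough to test: 1 of 13 for neutrophils, 1 of 20 for lymphocytes and 1 of 16 erythroid genes. A lone gene of a list does not show whether such cells were present. In the macrophage list 4 of 26 members were tested. Of these the lipopolysaccharide co-receptor Cd14 was 2.96-fold higher in Met fl/fl. Csf1r, which no Met fl/fl array detected, was at least 1.47-fold higher in Egfr fl/fl, a call that ended without Met fl/fl replicate 2 (limma adjusted p = 0.0614) or replicate 3 (0.0704). The log2 intensity of Csf1r was 5.97 on Egfr fl/fl replicate 3, against 5.40 and 5.13 on replicates 1 and 2. The tested neutrophil gene, Lcn2, a secreted lipocalin, read 14.29 ± 0.07 (SD, n = 3) in Egfr fl/fl and 9.49 ± 0.16 in Met fl/fl, a 27.9-fold difference (adjusted p = 3.63e-09). The tested lymphocyte gene, Lck, differed by 0.028 ± 0.28 (SE) and did not pass. The carbonic anhydrase gene Car2, from the erythroid list, was at least 1.23-fold higher in Met fl/fl at an adjusted p of 0.0483, and that call ended without Egfr fl/fl replicate 1 (0.133), replicate 2 (0.0936) or replicate 3 (0.0761), without Met fl/fl replicate 2 (0.146) or replicate 3 (0.110), and with other settings such as median scaling (0.260).

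Genes of the pathways that run through the floxed receptors did not pass as lists. Of 13 tested EGF family ligands, receptors and regulators 1 was higher in Met fl/fl and 5 in Egfr fl/fl, 6 passing when adjusted over the list alone (median -0.09, adjusted p = 0.382). Without Egfr fl/fl replicate 3 the counts were 2 and 5 and the median -0.20. The feedback inhibitors Lrig1 and Errfi1 were 2.22-fold and 2.19-fold higher in Egfr fl/fl. In the HGF and MET list 1 of 15 members was higher in Met fl/fl and 5 in Egfr fl/fl, 6 passing when adjusted over the list alone (median -0.22, adjusted p = 0.334). Without Egfr fl/fl replicate 3 the counts were 3 and 6 and the median -0.083. Its members included Spint1, an inhibitor of HGF activation, at least 1.99-fold higher in Met fl/fl, and the urokinase receptor Plaur, 2.49-fold higher in Egfr fl/fl. ERK feedback and immediate early genes counted 4 of 21 higher in Met fl/fl and 11 in Egfr fl/fl, with 15 passing when adjusted over the list alone (median -0.30, adjusted p = 0.0616). Klf4 was 2.44-fold higher in Met fl/fl, with its other probes at 2.46 and 2.39 on the log2 scale, and Spred1, an inhibitor of the pathway, 2.56-fold higher in Egfr fl/fl. The list passed without Met fl/fl replicate 3 (camera adjusted p = 0.0405) and with dim probes kept (0.0123). It also passed with only probes at a detection p under 0.01 on all 6 arrays (0.0449).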

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

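The robust negative-control estimate and the fit with Egfr fl/fl replicates 1 and 2 both left out were chosen after seeing the data; the other settings were planned. Median scaling called 2353 genes, 1131 of them higher in Met fl/fl, and gave -0.39 for Egfr (adjusted p = 0.348). Array weights called the most genes, 5261, with 2926 higher in Met fl/fl and 2335 higher in Egfr fl/fl. With Egfr fl/fl replicates 1 and 2 both left out 1264 genes were higher in Met fl/fl and Egfr differed by -0.52 (adjusted p = 0.0663). The Egfr call was also lost with no filter (-0.43, adjusted p = 0.0866), with no variance trend (-0.43, adjusted p = 0.0588) and with array weights (-0.29, adjusted p = 0.0519); no filter adds dim probes to the adjustment, and for the rest the cause was not tested. It was kept in 11 of 20 alternatives, over which its adjusted p ranged from 0.0282 to 0.348. Leaving out each array in turn gave 2555 to 4390 genes, 1381 to 2454 higher in Met fl/fl, 1174 to 1936 higher in Egfr fl/fl, 7 to 8 lists and -0.55 to -0.36 for Egfr, with the lowest gene counts without Met fl/fl replicate 2 and the highest without Egfr fl/fl replicate 3. An estimated correlation left 0 lists and fry gave 21, since fry does not compare a list with other genes. Over the 1000 most variable probes, mean r between groups was 0.275, against 0.906 over all tested probes. Of the named genes only Lck, never called, changed sign: -0.0045 with no background correction, -0.0055 with the deposited values, -0.19 with median scaling, -0.023 with cyclic loess, -0.32 with Egfr fl/fl replicates 1 and 2 both left out, and -0.076, -0.037 and -0.32 without Egfr fl/fl replicate 1, Egfr fl/fl replicate 2 and Met fl/fl replicate 2, against 0.23 without Met fl/fl replicate 1; the cause was not tested. Over all settings, Egfr apart, 2633 values of named genes kept their side of the threshold and 81 lost it, and 692 values of lists kept it, 11 lost it and 19 gained it. Signal over background limits the Met probe and every gene near the detection limit, where folds are bounds.

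With the replicate number as a block 3882 genes passed. The labels do not say whether the numbers pair the arrays, and deviations of 3 arrays from their own mean are too constrained to decide it. Deviations of same-numbered arrays from their group means correlated at 0.24, -0.15 and 0.32, and Egfr fl/fl replicate 2 correlated best with Met fl/fl replicate 1 (0.34). The block ended the call of Car2 (adjusted p = 0.0630) and of no other named gene or list.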

Other observations

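Other signalling and tissue lists, not past the threshold as lists, held large differences between members. In the WNT list 3 of 19 members were higher in Met fl/fl and 9 in Egfr fl/fl (median -0.50, adjusted p = 0.182); next to Wnt4, the target gene Axin2 was at least 2.00-fold higher in Met fl/fl, while Sp5 was at least 5.62-fold higher in Egfr fl/fl. NOTCH pathway genes counted 4 of 15 higher in Met fl/fl, among them the receptor Notch2 (at least 5.12-fold, detected on 2 Egfr fl/fl arrays) and the target Hey1 (3.24-fold), and 1 higher in Egfr fl/fl, the ligand Jag1 (2.17-fold; adjusted p = 0.103 with Egfr fl/fl replicate 3 alone), with a list adjusted p of 0.483. Without Egfr fl/fl replicate 3 the NOTCH counts were 6 and 2, and with it alone the median was -0.013 against 0.14. TGF beta pathway genes split as 8 of 21 higher in Met fl/fl and 5 in Egfr fl/fl (adjusted p = 0.720), with Inhba 4.39-fold higher in Met fl/fl and Tgfb2 7.46-fold higher in Egfr fl/fl. In the list of the epithelial to mesenchymal transition 4 of 12 were higher in Met fl/fl and 5 in Egfr fl/fl (adjusted p = 0.667), and in the extracellular matrix list 3 of 17 and 7 (adjusted p = 0.348). Sparc was 5.54-fold and the laminin gene Lamb3 4.61-fold higher in Met fl/fl, and Tnc, tenascin C, at least 19.4-fold higher in Egfr fl/fl. AKT and STAT3 genes counted 5 of 21 higher in Met fl/fl, led by Socs3 (2.70-fold), and 3 in Egfr fl/fl (adjusted p = 0.720). Interferon response genes counted 6 of 18 and 3 (adjusted p = 0.465), and MHC genes 1 of 7 and 1 (adjusted p = 0.720; 1 and 2 without Egfr fl/fl replicate 3).

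Oxidative phosphorylation genes were higher in Met fl/fl in 12 of 34 members and in Egfr fl/fl in 2 (median 0.11, adjusted p = 0.362), cytosolic ribosomal protein genes in 4 of 36 and 1 (median 0.05, adjusted p = 0.720), and genes of fatty acid synthesis and oxidation in 6 of 20 and 2 (adjusted p = 0.720). These depended on Egfr fl/fl replicate 3: without it the counts were 12 and 6, 4 and 4, and 7 and 5, and the medians 0.0036, 0.00095 and 0.050. In glycolysis 4 of 13 were higher in Met fl/fl and 4 in Egfr fl/fl (adjusted p = 0.720): Pkm was 2.04-fold higher in Met fl/fl and Pfkp 5.24-fold higher in Egfr fl/fl. NRF2 and xenobiotic genes counted 5 of 25 and 7 (adjusted p = 0.354), with Gsta1 at least 2.93-fold higher in Met fl/fl although Gsta3 was far higher in Egfr fl/fl. Among p53 targets 4 of 20 were higher in Met fl/fl and 5 in Egfr fl/fl (adjusted p = 0.720), with a median of 0.16 and a mean of -0.24; Mdm2 was 2.00-fold higher in Met fl/fl and Gadd45a 4.70-fold higher in Egfr fl/fl. Imprinted genes were higher in Egfr fl/fl in 7 of 9 members and in Met fl/fl in 1 (median -0.63, adjusted p = 0.0983). Sex-linked transcripts counted 1 of 7 higher in Met fl/fl and 2 in Egfr fl/fl (adjusted p = 0.902), with a median of 0.27 and a mean of -0.31. The Y-linked gene Eif2s3y was detected on all 3 Egfr fl/fl arrays and 0 Met fl/fl arrays, at least 8.15-fold higher in Egfr fl/fl. Kdm5d and Uty, also Y-linked, were detected on all 3 arrays of each group. So was 1 probe of the Y-linked gene Ddx3y, at a mean log2 intensity of 9.14 in Egfr fl/fl and 9.56 in Met fl/fl. Other Ddx3y probes were detected on 0 arrays. Xist was detected on 0 Met fl/fl arrays and by 1 of its probes on 1 Egfr fl/fl array.

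The tests of local gene density and of the chromosome with Egfr fl/fl replicate 3 alone were set before their results were seen, and the other tests here were chosen after. Of the 10 splits of the 6 arrays into 3 and 3, only the real split, 1 of the 10, called as many genes by limma: 3543, against 0 for the highest of the others. At an unadjusted p under 0.05 the counts were 4307 and 973, and the split with 973 set Egfr fl/fl replicates 1 and 2 and Met fl/fl replicate 1 against the rest. With 10 splits the share cannot fall below 0.1.

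Egfr fl/fl replicate 3 lay 0.179 of the way from replicates 1 and 2 to the Met fl/fl arrays on the first component. Carry-over of Met fl/fl RNA is argued against by 17 probes that were bright on the Met fl/fl arrays and not detected on Egfr fl/fl replicates 1 and 2: on replicate 3 they gained a median share of 0.00523 of the Met fl/fl level (quartiles -0.00214 and 0.0178). Whether a distortion that depends on brightness contributed could not be decided. A smooth curve on brightness took 0.000846 of the variance of the differences of replicate 3, but quantile normalization had already given every array the same distribution. A component specific to probes and shared with the Met fl/fl arrays may contribute: over 2208 genes, which are not independent, the difference between a gene's 2 brightest probes moved together in replicate 3 minus replicate 1 and in Met fl/fl minus replicate 2, with r = 0.476 (95% bootstrap interval 0.421 to 0.528), against 0.0478 (0.00477 to 0.0902) for replicate 2 minus replicate 1 and Met fl/fl minus replicate 3. That r cannot separate such a component from a shift of whole genes, because the offset compresses the differences of dimmer probes. Nor can r tell it from a component confined to replicates 1 and 2, which would enter both differences with the same sign. Replicate 2 minus replicate 1 cancels what those 2 arrays share, so the low r there is no control for it. Different transcript ends or isoforms, a distortion that depends on brightness and an unrecorded processing batch stay open, as does a difference in the state of the cells, and no biological explanation was tested.

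Genes on chromosome 19 were shifted towards Met fl/fl: over 319 tested genes the median log2 difference was 0.29 and 68.3% were higher in Met fl/fl. The shift passed against 10000 brightness-matched random gene sets (adjusted p = 0.001 over 20 chromosomes, from the smallest share the sets can give), under the assumption that genes vary independently. So did 5 other chromosomes with smaller shifts in either direction. Among these, chromosome 6, which carries Met, had a median of -0.085 (adjusted p = 0.001 by the random sets). Chromosome 11, which carries Egfr, had a median of 0.14 (adjusted p = 0.0288). Whether these shifts relate to the floxed alleles was not tested. For chromosome 19 local gene density is argued against, since the excess over density-matched sets was 0.19 against 0.23 over brightness-matched ones. The component that sets Egfr fl/fl replicates 1 and 2 apart is also argued against as the whole cause, with an excess of 0.22 when replicate 3 was the only Egfr fl/fl array, although it did shift the chromosome: replicate 3 minus replicates 1 and 2 had a median of 0.098 there, above 99.8% of random sets. A copy-number step over the whole chromosome could not be decided: of 7 stretches 2 had medians of 0.53 and 0.50 with widened intervals above 0, and the lowest median was -0.083 (widened interval -0.26 to 0.41). By its unwidened 95% interval that lowest stretch lay below the chromosome's median (upper limit 0.25 against 0.29). This interval makes no allowance for picking the lowest of 7 stretches, so it does not decide about a step. The unwidened upper limit of another stretch equalled the chromosome's median. A step over part of the chromosome, GC content, which needs a genome, and regulation shared by neighbouring genes stay open, and no biological explanation other than the step was tested.

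Passenger DNA beside a floxed allele, carried along from the embryonic stem cells or strain in which it was made, would raise the share of called genes near Egfr and Met. Of the 97 tested genes nearest to either gene, up to 25 on each side, 39 (40.2%, exact 95% interval 30.4% to 50.7%) passed the threshold, against 41.4% of the other genes placed on a chromosome. The ratio was 0.972, with an upper limit of 1.22, which argues against an excess of 1.5 times. Lists of neighbours fixed before the data were examined gave 5 of 15 genes near Met higher in Met fl/fl and 3 in Egfr fl/fl (adjusted p = 0.865; 5 and 5 without Egfr fl/fl replicate 3, with a median of 0.16 against 0.25), and 7 of 29 near Egfr higher in Met fl/fl and 6 in Egfr fl/fl (adjusted p = 0.753), the latter with a median of 0.05, or -0.0014 without Egfr fl/fl replicate 3, and a mean of -0.003. A few altered genes beside either locus stay possible, and no explanation other than passenger DNA was tested.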
